A study of Mus musculus with 6 samples.

How the data were processed

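The series holds polyA-selected RNA-seq of mouse hippocampus from 6 libraries, 3 of the corn oil group and 3 of the BBP group (50 mg/kg/day, age 4 months). Per the labels' protocols, RNA was extracted with Trizol, selected with oligo(dT), and made into strand-marking (dUTP) paired-end libraries with adapters that carry molecular identifiers, sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, UMI-tools, StringTie 2.1.6, DESeq2, edgeR and the mm10 build, with no role or order for each. Grouping follows the labels. No sample was left out.

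Per the file headers, the deposited table gives estimated counts and FPKM for every gene and library, with Ensembl gene IDs, symbols, coordinates and annotation terms. The deposited estimated counts are whole numbers. In every library more genes had a count of 4 than of 3 or 5, and slightly more had 8 than 7 (423 against 382 in corn oil library 1). From this, about 4 counts were assumed to stand for 1 fragment, although a count of 3 was more frequent than 8. How they were made and which strand setting was used in counting are not given in the sources used here, so genes that overlap on either strand are uncertain. The deposited FPKM values were used as given. Of 31838 gene IDs, 31739 (99.69%) were found in GENCODE M21, and 90.79% of these had identical coordinates there. Transcript lengths were those of the longest transcript of each gene in that annotation, which need not be the one expressed. At the assumed 4 counts per fragment, the counts over genes would equal 15619401 to 17105590 fragments per library. Each library had 25304 to 25931 genes above 0. The standard errors given are those of the fits, which include the spread between libraries.

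Genes were compared with edgeR 4.0.16 in R 4.3.3 on the estimated counts (TMM normalization, filterByExpr, quasi-likelihood F test, treatment as the only term, Benjamini-Hochberg adjusted p under 0.05). The standard error was taken as the absolute log2 fold change over the square root of F. The biological coefficient of variation was 0.225. A looser description, with no control of the false discovery rate, took genes at an unadjusted p under 0.05 with an absolute log2 fold change of at least 1. The 47 gene lists, written together with the tests before any value was seen, were tested with camera of limma 3.58.1 (preset correlation 0.01, lists with at least 5 tested genes, adjusted over lists), with camera at an estimated correlation, and with fry, which asks whether a list's own genes shift, without reference to other genes. The sex-linked list (Xist and Y-linked genes) was described only. GO, KEGG and Reactome terms with 15 to 300 tested genes were tested with camera, adjusted within each kind. List medians per library use log2 CPM (prior count 2) minus the corn oil mean. Exact permutation tests over the 10 splits of the libraries were used for list means and for the distance between groups, which is Euclidean on log2(FPKM + 1).

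The genes named were set by a rule: in each direction, genes past the threshold, filled up to 10 by smallest p among annotated genes whose groups do not overlap, without predicted or clone-named genes, plus the 2 members with the smallest p of each list and the 2 with the highest mean FPKM of each cell type list. Some genes that this rule selects are not reported here. A group at 0 in every library was compared with a floor of 3 fragments, or 12 deposited counts, per library. Values of the named genes are means and SD over 3 libraries.

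The scripts were tested on simulated data with the means, dispersions and library sizes of these libraries, in which 200 of 20428 genes were changed. Of 50 genes at each fold, 7 were recovered at 1.5-fold, 28 at 2-fold, 33 at 4-fold and 45 at 8-fold, and 12 unchanged genes were called. A list shifted by 0.4 on the log2 scale was recovered, and 0 of 47 unshifted lists were called by camera. The simulated genes vary independently, which real genes do not.

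The alternatives set before the data were examined were limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1, the same with a pseudocount of 0.1 or 0.5, with no filter, with a mean FPKM of at least 5, rescaled to TPM, quantile normalized, without trend, robust, or with array weights, and then DESeq2 1.42.0, edgeR with median-of-ratios size factors, a replicate block, a fit without predicted genes, and fits without each library. Terms of 5 to 500 genes and a Spearman distance were also among them. After the data were seen, 6 fits were added: counts divided by 4, edgeR without a filter, robust edgeR, a fit without mitochondrial genes and their nuclear copies, a fit without BBP libraries 1 and 2, and a transcript length correction. Files were read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.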

Results

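Polyadenylated RNA was sequenced from the hippocampus of C57BL/6 mice aged 4 months that had received either corn oil, as the control, or butyl benzyl phthalate (BBP), a plasticiser, at 50 mg/kg/day. Each group held 3 libraries, named here by group and replicate number. The title of the series ties BBP to cognitive impairment, and the comparison asks how the hippocampal transcriptome of treated mice differed from that of control mice. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries. The deposited estimated counts summed to 63079584, 62747522 and 68422361 in corn oil libraries 1 to 3 and to 63449046, 62477604 and 67270275 in BBP libraries 1 to 3. About 4 deposited counts were assumed to stand for 1 fragment, a ratio read from the low counts only and not known from the sources used here. Under this assumption, the counts over genes would equal 15619401 to 17105590 fragments per library. Y-linked Ddx3y had 1991 to 3179 counts in every library and Xist, the X-inactivation RNA, had 0 to 24, so all 6 libraries had the profile of male tissue.

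The 10 annotated genes with the smallest p among those higher in BBP included Gbp4, an interferon-inducible GTPase, at 0.378 ± 0.0166 FPKM (SD, n = 3) in corn oil and 0.640 ± 0.0985 in BBP. Apod, a lipid-binding protein secreted by oligodendrocytes, stood at 44.8 ± 4.59 and 58.4 ± 2.19 FPKM, and Padi2, a protein-citrullinating enzyme, at 4.21 ± 0.175 and 5.37 ± 0.164. On the lower side, Ttr, which encodes the thyroid hormone carrier transthyretin, averaged 188 ± 155 FPKM in corn oil and 51.5 ± 6.98 in BBP, and Sncg, which encodes gamma-synuclein, averaged 3.42 ± 0.909 and 1.42 ± 0.137. Vcp-rs, a sequence related to the ATPase gene Vcp, averaged 18.1 ± 1.56 and 10.5 ± 0.761 FPKM. None of these differences passed edgeR's test over all genes, and among them only Vcp-rs passed DESeq2's (adjusted p = 0.000171).

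Of 31838 genes in the table, 20428 were tested, and 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test (smallest adjusted p = 0.953). At an unadjusted p under 0.05 there were 685 genes, 405 higher and 280 lower, where 1021 would be reached by chance. That count was 393 without corn oil library 1, 1475 without BBP library 1 and 1530 without BBP library 3. Limma on the FPKM values called 0 genes as well, with 396 at an unadjusted p under 0.05. DESeq2 called 4, chosen here after their values were seen: Arhgap36, Vcp-rs and the predicted gene Gm2004 lower, and the predicted gene Gm2274 higher. The 3 BBP values lay entirely on one side of the 3 corn oil values for 10.4% of the tested genes, against 10% by chance. The looser description of an unadjusted p under 0.05 with at least a 2-fold difference took in 146 genes, 89 higher and 57 lower, of which 76 were predicted or clone-named. It took in 247 genes without BBP library 1, 299 without BBP library 3 and 4 to 24 in the limma fits. The 95% interval of the fold change lay within 2-fold in either direction for 14279 genes, or 69.9% of those tested, and the median standard error was 0.181 on the log2 scale. The edgeR call of 0 genes became 1 without corn oil library 2 (Zbtb12, higher) and 3 without BBP library 1 (Scgb1a1, Commd1b and the predicted gene Gm45062), names that were likewise picked after the fact.

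Among the 10 genes named on the higher side (mm10 coordinates), Gbp4 (chromosome 5, 105115767 to 105139586) had a log2 fold change of 0.77 ± 0.17 (SE). Lrrc74b (chromosome 16, 17544465 to 17561247) had 1.66 ± 0.40 and Zfp82, a zinc-finger gene (chromosome 7, 30054489 to 30072804), had 1.05 ± 0.25. Lrrc74b was at a low level, with 15 to 44 deposited counts in corn oil and 78 to 98 in BBP. The values of Asap2 (an Arf GTPase-activating protein), Plekhg1, Apod, Padi2, Fhdc1 (a formin) and Nr2c2 (an orphan nuclear receptor) ranged from 0.37 for Padi2 to 0.81 for Nr2c2. Glrp1 had 0, 3 and 0 counts in the corn oil libraries and 18, 27 and 17 in the BBP libraries, a level of few fragments in either group. All of these genes had an adjusted p of 0.953.

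Vcp-rs (chromosome X, 104345829 to 104348234, minus strand) had a log2 fold change of -0.76 ± 0.12 (SE) and the same adjusted p of 0.953 in edgeR, against 0.000171 in DESeq2. Its parent gene Vcp was at 47.8 FPKM in corn oil and 45.7 in BBP, and because fragments of near-identical copies can be split between them the value of Vcp-rs is uncertain. Arhgap36 (chromosome X, 49463945 to 49500244), had -1.61 ± 0.32, with an adjusted p of 0.953 in edgeR and 0.0408 in DESeq2. Sncg (chromosome 14, 34370274 to 34374789) had -1.23 ± 0.27, Adamts20, a secreted metalloprotease gene, had -0.83 ± 0.18, and Aprt, the purine salvage enzyme gene, had -0.49 ± 0.12. Lnp1, Ano2 (a calcium-activated chloride channel gene) and Hebp2 had -1.57 ± 0.42, -0.99 ± 0.26 and -0.73 ± 0.20. Lnp1 was at a low level, with 43 to 104 deposited counts in corn oil and 19 to 25 in BBP. Ttr (chromosome 18, 20665280 to 20674321) had -1.84 ± 0.49, and its FPKM of 81.4, 115 and 366 in corn oil libraries 1 to 3 compared with 51.5, 44.5 and 58.5 in BBP libraries 1 to 3. Without corn oil library 3 the log2 fold change of Ttr was -0.92. Glycam1, a mucin-like ligand of L-selectin, had 15, 11 and 13 counts in corn oil and 0 in each BBP library, which is at least 1.07-fold lower against a floor of 3 fragments, or 12 deposited counts, per library.

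**Figure D1:**
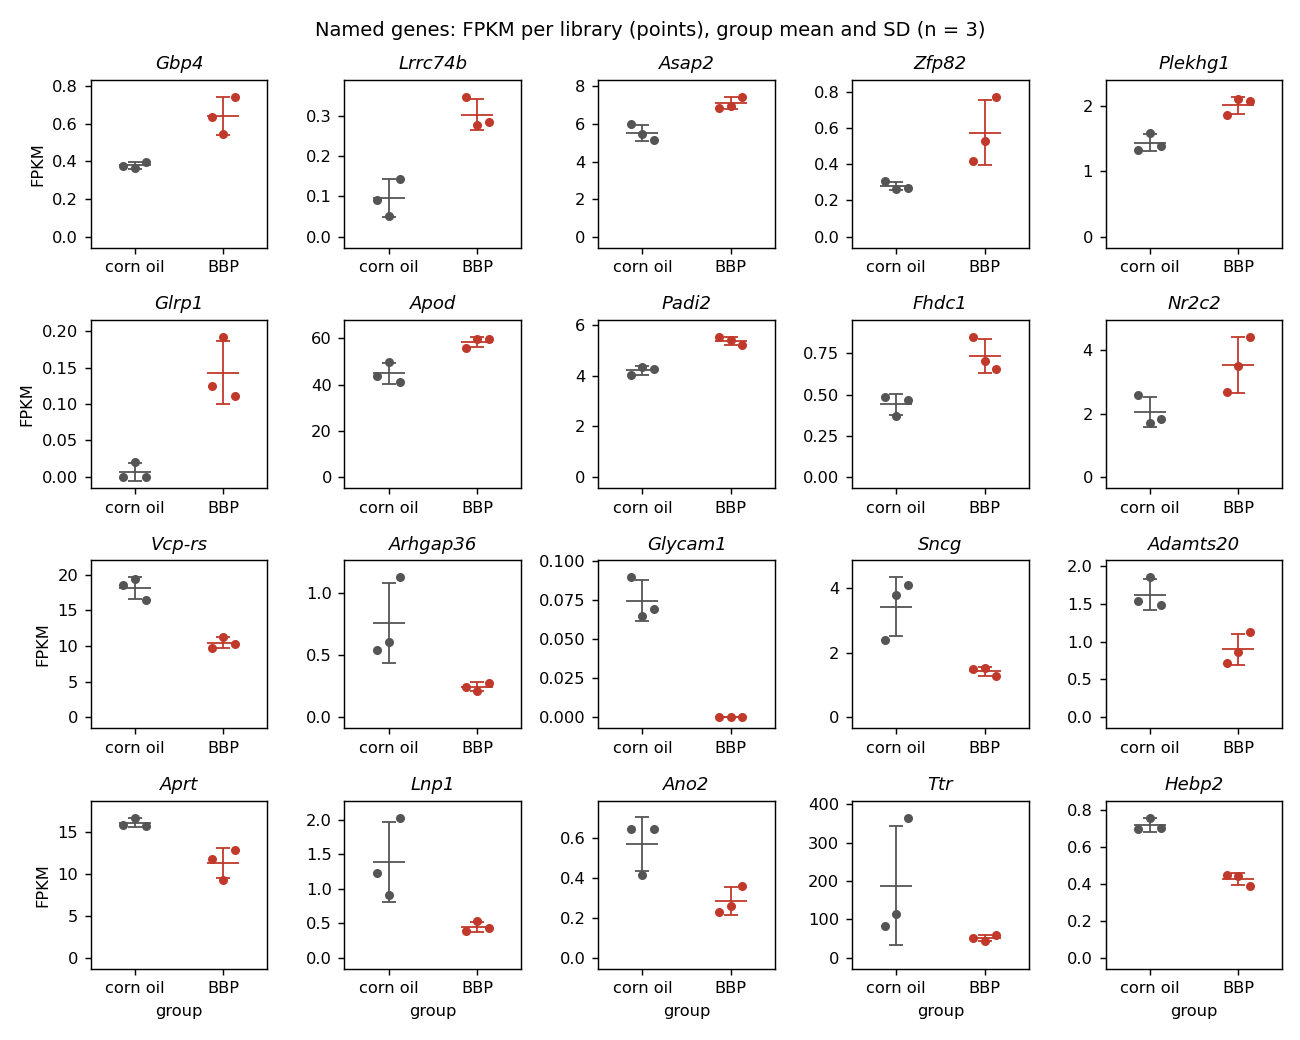
FPKM of the 20 genes named by the fixed rule (y axis, linear scale) in the corn oil and BBP groups (x axis), with points for single libraries, a dash for the group mean and bars for the SD (n = 3). In each panel the groups do not overlap, and no gene passed the adjusted threshold in edgeR (adjusted p = 0.953).

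The BBP libraries differed more from one another than the corn oil libraries did. Over the tested genes, the mean distance between libraries on the log2(FPKM + 1) scale was 27.8 within corn oil and 44.0 within BBP, and it was 36.1 between the groups. The between-group mean exceeded the within-group mean by 0.2, which was not distinguishable from other splits of the 6 libraries (exact permutation test, one-sided p = 0.4, where 0.1 is the smallest value 3 against 3 allows). The difference was -4.04, -3.84 and -3.65 without corn oil libraries 1, 2 and 3, and 4.07, 1.99 and 6.67 without BBP libraries 1, 2 and 3. BBP library 3 lay closer to corn oil library 1, at 26.3, than to BBP library 1, at 41.6, or BBP library 2, at 41.0.

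Genes for the protein-making and respiratory machinery were lower in BBP as lists. Of 72 cytosolic ribosomal protein genes, 66 had a negative log2 fold change, with a list median of -0.21, and of 49 nuclear genes for oxidative phosphorylation, 48 did, with a median of -0.18. Rpl7a averaged 45.4 ± 6.88 FPKM (SD, n = 3) in corn oil and 31.9 ± 6.12 in BBP, Rpl17 32.7 ± 7.03 and 24.2 ± 3.21, and the complex I subunit gene Ndufc1 17.4 ± 0.423 and 12.3 ± 3.62. The 13 mitochondrially encoded mRNAs moved the other way, with 12 positive and a median of 0.25. These shifts were uneven across the treated libraries. Relative to the corn oil mean, the ribosomal list median was 0.02 in BBP library 1, -0.49 in BBP library 2 and -0.17 in BBP library 3, and the oxidative phosphorylation list stood at 0.01, -0.40 and -0.17. The mitochondrial mRNAs stood at 0.74 in BBP library 2, at -0.02 in BBP library 1 and at -0.12 in BBP library 3. Mitochondrial genes took 11.5% of the counts of BBP library 2 and 7.11% to 8.57% of those of the other libraries.

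In camera with the preset correlation, the ribosomal list had an adjusted p of 1.06e-14, the oxidative phosphorylation list 3.42e-13 and the mitochondrial list 0.0170. With an estimated correlation none of these calls held (adjusted p = 0.566 for the ribosomal and oxidative phosphorylation lists and 0.716 for the mitochondrial one). No member passed the test over all genes or adjusted over the list alone. Over libraries, the mean of the ribosomal list differed by -0.21 between groups (SD 0.0393 in corn oil and 0.246 in BBP, n = 3 each, exact permutation test, two-sided p = 0.3). Without BBP library 2 the list medians were -0.07 (ribosomal), -0.07 (oxidative phosphorylation) and -0.07 (mitochondrial, adjusted p = 0.0521), so that the mitochondrial list turned, and its call also ended without corn oil library 1 (adjusted p = 0.169) or 2 (adjusted p = 0.0541). Without BBP library 1 the medians of the ribosomal and mitochondrial lists were -0.33 and 0.37, and without BBP library 3 the mitochondrial median was 0.40. Ribosomal protein genes and mitochondrial genes have many near-identical copies in the genome, so the level of single members is uncertain.

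Myelin genes were higher in BBP as a list: all 30 oligodendrocyte and myelin markers had a positive log2 fold change, with a median of 0.37. Mbp, the gene for myelin basic protein, averaged 214 ± 34.9 FPKM (SD, n = 3) in corn oil and 288 ± 68.1 in BBP. The libraries did not follow the groups throughout. The list median was 0.50 in BBP library 1 and 0.57 in BBP library 2, but -0.10 in BBP library 3, below the 0.26 of corn oil library 2. BBP library 2 is the library with the largest ribosomal and mitochondrial shifts above, and BBP library 1 the one with high striatum and isocortex markers below. Whether the myelin difference is tied to these was not tested. Apod, which belongs to the list, and Padi2, which does not, were among the genes named above. Microglia markers were positive for 23 of 27 genes with a median of 0.17, P2ry12 standing at 8.93 ± 1.33 and 10.6 ± 0.961 FPKM. Astrocyte markers, with 19 of 23 positive and a median of 0.06, did not pass (adjusted p = 0.0571).

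The myelin list had a camera adjusted p of 4.85e-14 with the preset correlation and the microglia list 0.0147. Both had an adjusted p of 0.566 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The myelin list had a median of 0.24 without BBP library 2. With both BBP library 1 and BBP library 2 left out, a choice made after seeing the data that leaves 1 treated library, the myelin median was -0.11 (adjusted p = 0.103). The microglia call ended without corn oil library 1 (adjusted p = 0.104) or BBP library 1 (median 0.09, adjusted p = 0.112).

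Striatum and isocortex markers were higher in the BBP group, and 1 library carried the difference, while thalamus and habenula markers had a median of -0.07 (adjusted p = 0.813). Of 21 striatum markers, 20 had a positive log2 fold change with a median of 0.53, and of 25 isocortex markers 19 did with a median of 0.35. Relative to the corn oil mean, the striatum median was 1.60 in BBP library 1 and -0.10 and -0.31 in BBP libraries 2 and 3, while the isocortex median was 0.88, -0.01 and -0.12. Adora2a, the adenosine receptor gene of striatal neurons, had 6.67 FPKM in BBP library 1 and 0.444 to 1.01 in the other 5 libraries. Lamp5 had 64.5 FPKM in BBP library 1 and 14.6 to 20.7 in the others. In the same library the medians of the hippocampal field markers were low, at -0.75 for dentate granule neurons, -0.75 for CA1 pyramidal neurons and -0.77 for CA2 and CA3 pyramidal neurons. In BBP libraries 2 and 3 these medians were 0.38 and 0.14, 0.14 and 0.18, and -0.04 and -0.06, the last 2 within the range of the corn oil libraries. BBP library 1 thus carried the lower CA2 and CA3 list in BBP, where 11 of 14 members were negative with a median of -0.20. Bok averaged 33.0 ± 5.02 FPKM (SD, n = 3) in corn oil and 22.9 ± 7.20 in BBP.

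The striatum, isocortex and CA2 and CA3 lists passed camera with the preset correlation (adjusted p = 0.00177, 0.00417 and 0.0238). With an estimated correlation the adjusted p was 0.676, 0.566 and 0.654. Without BBP library 1 the striatum median was -0.37 (adjusted p = 0.0759), the isocortex median 0.02 (adjusted p = 0.704) and the CA2 and CA3 median -0.02 (adjusted p = 0.919). The CA2 and CA3 call also ended without corn oil library 1 (median -0.12, adjusted p = 0.116) or 2 (adjusted p = 0.0527), and its median was -0.40 without BBP library 2. Isocortex and striatum medians were 0.53 and 0.89 without BBP library 3. A transcript length correction, chosen after the data were seen, ended the isocortex and the CA2 and CA3 calls (adjusted p = 0.0690 for each) with medians about as large, 0.32 and -0.22. The CA2 and CA3 call ended in 12 of 25 other fits in all.

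**Figure D2:**
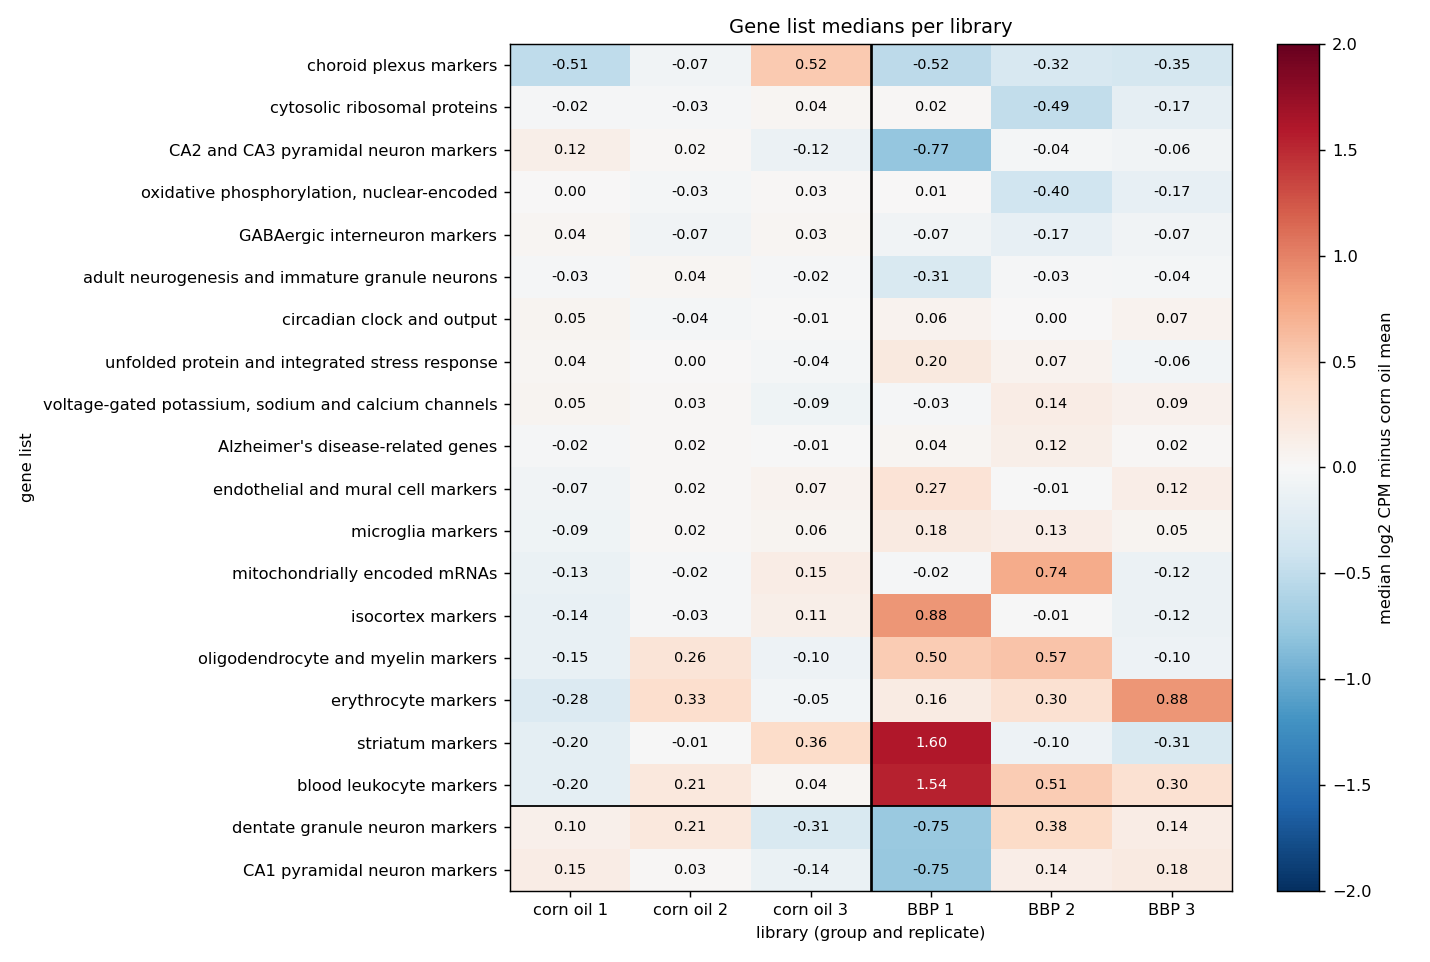
Median over each list's genes of log2 CPM minus the corn oil mean (colour and printed value), for the 18 lists called by camera with the preset correlation and, under the line, for 2 hippocampal field lists that were not called; columns are single libraries. BBP library 1 stands at 1.60 for striatum markers and BBP library 2 at -0.49 for ribosomal proteins.

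Choroid plexus and vascular lists moved in opposite directions. Choroid plexus markers were lower in BBP, with 20 of 23 negative and a median of -0.49, but corn oil library 1 was at -0.51, BBP libraries 1 to 3 at -0.52, -0.32 and -0.35, and corn oil libraries 2 and 3 at -0.07 and 0.52. Endothelial and mural cell markers were positive for 24 of 30 genes with a median of 0.17, among them Flt1, a VEGF receptor gene, at 2.31 ± 0.0615 FPKM (SD, n = 3) in corn oil and 2.88 ± 0.434 in BBP, and Abcc9, a potassium channel subunit gene of mural cells, at 0.563 ± 0.0668 and 0.862 ± 0.125. Of 8 erythrocyte markers 7 were positive, with a median of 0.46. Hba-a2, an alpha-globin gene, averaged 48.9 ± 9.82 and 69.6 ± 16.8 FPKM, and its near-identical copies make its own level uncertain. Of 22 blood leukocyte markers 8 were tested, and 6 of these were positive with a median of 1.08. Their levels were low, with 1 of the 8 at a mean of at least 1 FPKM in corn oil, and 2 of them belong to another list as well. The T cell receptor gene Trbc2 had 13.6 FPKM in BBP library 1 and 0.217 to 0.751 in the others. Ighm, which is in the isocortex list as well, had 18.7 FPKM in BBP library 1 and 3.73 to 8.85 in the others. The leukocyte median was 1.54, 0.51 and 0.30 in BBP libraries 1 to 3. BBP library 1 is also the library with high striatum and isocortex markers, so its part of the rise was not told apart from that regional difference.

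The adjusted p in camera was 9.45e-05 for choroid plexus, 0.00813 for endothelial and mural cells, 0.0147 for erythrocytes and 0.0406 for leukocytes. With an estimated correlation it was 0.566 for 3 of these lists and 0.567 for the erythrocyte list. The choroid plexus call ended in 9 of 24 other fits, which were the fit without corn oil library 3 (median -0.07, adjusted p = 0.107) and 8 limma fits (with array weights, a median of -0.02 and the highest adjusted p, 0.291). The endothelial call ended without corn oil library 1 (adjusted p = 0.0700), BBP library 1 (adjusted p = 0.239) or BBP library 3 (adjusted p = 0.0892). The erythrocyte call ended without corn oil library 1 (adjusted p = 0.112) or BBP library 3 (median 0.08, adjusted p = 0.544), and its median was 0.71 without corn oil library 2. The leukocyte call ended without corn oil library 1, 2 or 3 (adjusted p = 0.248, 0.170 and 0.0920) or BBP library 1 (median 0.30, adjusted p = 0.903), and the medians without corn oil library 3 and BBP library 3 were 0.58 and 0.39. It ended in 10 of 15 other fits, the length correction among them (median 1.11, adjusted p = 0.153).

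Lists tied to neuronal function and disease shifted by little. Voltage-gated channel genes were positive for 31 of 40 members with a median of 0.08, although the sodium channel subunit gene Scn4b owed its mean of 9.33 ± 8.74 FPKM (SD, n = 3) in BBP to 19.4 in BBP library 1. Genes related to Alzheimer's disease were positive for 24 of 31 members with a median of 0.10, Lrp1 standing at 16.0 ± 0.165 and 17.8 ± 0.779 FPKM. Unfolded protein and integrated stress response genes were positive for 26 of 31 with a median of 0.08, and circadian genes for 14 of 21 with a median of 0.03, which was -0.03 in limma after rescaling to TPM. Npas2, a clock transcription factor gene, averaged 4.85 ± 0.522 and 6.24 ± 0.893 FPKM, and Arntl 3.50 ± 0.223 and 4.19 ± 0.0790. GABAergic interneuron markers were negative for 18 of 23 genes with a median of -0.08, with Calb2, the calretinin gene, at 21.4 ± 1.38 and 13.9 ± 4.25 FPKM. Calb2, which is in the neurogenesis and the thalamus and habenula lists as well, had 9.71, 13.9 and 18.2 FPKM in BBP libraries 1 to 3. The interneuron markers with the highest FPKM, Sst and Cck, had log2 fold changes of -0.14 and -0.03. Genes of adult neurogenesis and immature granule neurons were negative for 19 of 32 with a median of -0.06, and Gal, the galanin gene, averaged 1.02 ± 0.266 and 0.338 ± 0.128 FPKM. Gal was at a low level, with 41 to 76 deposited counts in corn oil and 11 to 26 in BBP. Relative to the corn oil mean, the neurogenesis median was -0.31 in BBP library 1, where dentate granule markers were low as well, and -0.03 and -0.04 in BBP libraries 2 and 3.

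These 6 lists passed camera with the preset correlation at adjusted p = 0.00988 (channels), 0.0238 (Alzheimer's disease), 0.0246 (unfolded protein), 0.0238 (circadian), 0.0147 (interneurons) and 0.0497 (neurogenesis). None passed with an estimated correlation, where the adjusted p was 0.676 for the unfolded protein list and 0.566 for the other 5. The mean of the Alzheimer's disease list was higher in all 3 BBP libraries than in any corn oil library (difference 0.0819, SD 0.0359 in corn oil and 0.0198 in BBP, n = 3 each, exact permutation test, two-sided p = 0.1, the smallest possible). Of the 47 lists, 2 were separated in either direction, this list and the leukocyte list. By chance 10% of lists would be separated, which is more than were seen, so the separation does not single this list out. A transcript length correction, chosen after the data were seen, ended 5 of the 6 calls. The channel median fell to 0.03 (adjusted p = 0.313), while the others moved less, to 0.03 for circadian (adjusted p = 0.344), 0.07 for Alzheimer's disease (0.145), -0.07 for neurogenesis (0.145) and 0.07 for unfolded protein (0.0654). The neurogenesis call held in 4 of 25 other fits. Each of the 6 calls also ended when 1 of several libraries was left out. For the channels these were corn oil library 3 (adjusted p = 0.204) and BBP library 2 (median 0.05, adjusted p = 0.0863). For the Alzheimer's disease list they were corn oil libraries 1 and 3 (medians 0.11 and 0.09, adjusted p = 0.104 and 0.0745) and BBP libraries 2 and 3 (medians 0.07 and 0.13, adjusted p = 0.0774 and 0.0762). For the unfolded protein list they were corn oil library 3 (adjusted p = 0.204) and BBP library 1 (median 0.03, adjusted p = 0.670), and the median was 0.13 without BBP library 3. The circadian call ended without corn oil library 2 (median 0.00, adjusted p = 0.186), corn oil library 3 (median 0.11, adjusted p = 0.0745) or BBP library 1 (median 0.01, adjusted p = 0.320), and its median was 0.05, 0.06 and 0.18 without corn oil library 1, BBP library 2 and BBP library 3. The interneuron call ended without corn oil library 1 (adjusted p = 0.104), corn oil library 3 (adjusted p = 0.0745), BBP library 2 (median -0.04, adjusted p = 0.0755) or BBP library 3 (adjusted p = 0.0742), and the median was -0.14 and -0.13 without corn oil library 2 and BBP library 1. The neurogenesis call held without BBP library 2 (median -0.11, adjusted p = 0.00177) and ended without corn oil library 1 (median -0.09, adjusted p = 0.0700), 2 (-0.02, 0.191) or 3 (-0.08, 0.0745) and without BBP library 1 (-0.03, 0.563) or 3 (-0.04, 0.103).

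The lists closest to the known actions of phthalates were not called. PPAR targets and fatty acid oxidation genes, the program that phthalate metabolites switch on in rodent liver, had 21 positive and 16 negative members and a median of 0.02 (adjusted p = 0.991). Xenobiotic metabolism and AhR targets had a median of 0.04 (adjusted p = 0.599), the sex steroid and neurosteroid pathway -0.01 (0.991), glucocorticoid-responsive genes 0.01 (0.991) and thyroid hormone-responsive genes 0.10 (0.552). NRF2 targets and antioxidant enzymes had -0.06 (0.104), cholesterol synthesis 0.01 (0.991), p53 and DNA damage response 0.05 (0.991), apoptosis -0.02 (0.552), autophagy and lysosome -0.04 (0.991), and heat shock response 0.00 (0.773). Among immune lists, the pro-inflammatory cytokine and NF-kB response had 0.08 (0.991), the type I interferon response -0.05 (0.232), and complement and MHC 0.05 (0.474).

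Synaptic lists were also not called. Presynaptic vesicle release genes had a median of 0.08 (adjusted p = 0.103), postsynaptic density and plasticity genes 0.07 (0.132), glutamate receptors 0.01 (0.615) and GABA receptors, synthesis and transport 0.03 (0.811). Activity-regulated genes such as Fos and Arc had 0.03 (0.759), neurotrophin and growth factor signalling 0.05 (0.487), and acetylcholine and monoamine receptors 0.04 (0.991). Of the remaining lists, dentate granule neuron markers had -0.01 (0.759), CA1 pyramidal neuron markers -0.02 (0.433), oligodendrocyte precursor markers 0.09 (0.164), ependymal markers -0.01 (0.991), meningeal fibroblast markers 0.16 (0.963), thalamus and habenula markers -0.07 (0.813) and extracellular matrix genes 0.04 (0.764). In 6 of these uncalled lists, all with a median within 0.09 of 0, the median, the mean and the test differed in sign; the pro-inflammatory list, for example, had a positive median and mean and a negative test direction.

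In all, 18 of 47 lists passed camera with the preset correlation, 12 higher and 6 lower in BBP, and 0 passed with an estimated correlation or with fry (smallest adjusted p = 0.612 for a shift in either direction and 0.697 for mixed changes). Among the annotation terms carried by the deposited table, ribosome and respiratory chain terms were lower, as the lists were, and so were proteasome terms, which no list covered. Camera with the preset correlation called 68 of 2468 GO terms, 24 higher and 44 lower, 10 of 292 KEGG pathways, all lower, and 137 of 840 Reactome pathways, 11 higher and 126 lower. With an estimated correlation 0 terms of any kind passed (smallest adjusted p = 0.807 for GO, 0.493 for KEGG and 0.604 for Reactome). The KEGG ribosome pathway had a median log2 fold change of -0.17 over 132 genes, oxidative phosphorylation -0.16 over 125 and the proteasome -0.15 over 44. The KEGG Alzheimer disease pathway had a median of -0.10 over 166 genes, the opposite sign of the Alzheimer's disease list above, which is a different set of 31 genes. The KEGG Parkinson and Huntington disease pathways were lower as well (-0.14 and -0.12). How far these disease pathways fell through genes shared with oxidative phosphorylation was not tested, so whether the sign speaks against the list is left open. Central nervous system myelination was among the GO terms that were higher, with a median of 0.25 over 15 genes.

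**Figure D3:**
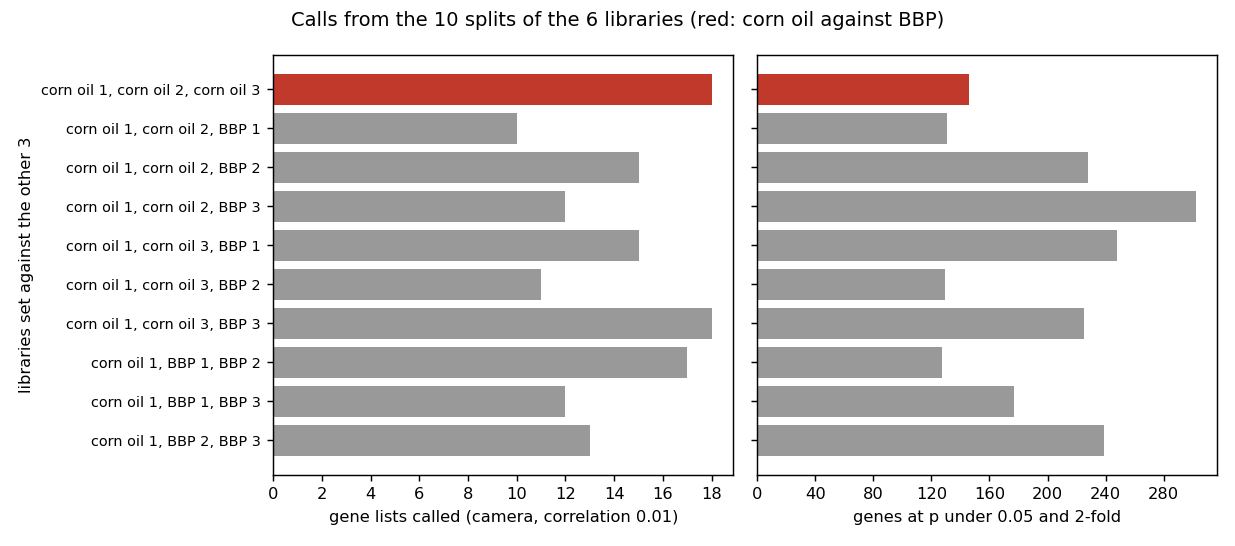
Number of gene lists called by camera with the preset correlation (left x axis) and of genes at an unadjusted p under 0.05 with at least a 2-fold difference (right x axis) for each of the 10 ways to part the 6 libraries into 3 and 3 (y axis, naming 1 side). The corn oil against BBP split (red) gave 18 lists and 146 genes, and the other splits gave up to 18 lists and 302 genes.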

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

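The tests with counts divided by 4, without a filter in edgeR, with robust edgeR, without mitochondrial genes and their nuclear copies, without both BBP libraries 1 and 2, and with a transcript length correction were chosen only after the result was seen. The count of genes past the threshold was 0 in edgeR (685 at an unadjusted p under 0.05) and stayed at 0 in 23 of 27 fits, the planned one included. It was 4 in DESeq2 (1 higher, 3 lower) and 10 without BBP libraries 1 and 2 (3 higher, 7 lower), a fit in which the lone BBP library is assumed to vary like the others. With 1 library left out it ranged from 0 to 3 (higher 0 to 1, lower 0 to 2). The labels do not say whether numbers shared between the groups pair the libraries. Deviations from the group means had correlations of -0.0771, 0.0756 and -0.102 between same-numbered libraries, which cannot decide this with 3 libraries per group. The replicate block called 0 genes (494 at an unadjusted p under 0.05), with 125 genes under the looser description and 17 lists.

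The looser description held 146 genes in edgeR. It held 9 in limma on log2(FPKM + 1), 24 with pseudocount 0.1, 12 with 0.5, 6 with no filter, 4 at a mean FPKM of at least 5, 19 rescaled to TPM, 9 quantile normalized, 9 with no trend, 9 robust and 6 with array weights, all of these testing fewer genes except the 1 with no filter. It held 64 without predicted genes, 60 on counts divided by 4, 352 in edgeR without filter, 367 without BBP libraries 1 and 2, and 195 to 299 with 1 library left out. The cause of these differences was not tested.

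Of 18 lists, 0 remained with an estimated correlation and 0 with fry. Of the GO, KEGG and Reactome terms, 0, 0 and 0 remained with an estimated correlation, while terms of 5 to 500 genes gave 61, 10 and 134. The number of lists called was 10 in limma with no filter, 10 with the transcript length correction and 10 to 16 with 1 library left out. The ribosomal and oxidative phosphorylation lists kept their call in all 25 fits that gave list tests besides the planned one. Over the lists called and their alternatives, 333 results kept the direction of the test and the call, 98 kept the direction of the test only and 7 turned. In 8 fits the median alone had the other sign, 7 for the circadian list in limma (down to -0.0336, rescaled to TPM) and 1 for the endothelial list (-0.0205, limma at a mean FPKM of at least 5). Over the named genes 1209 kept both, 2 passed the threshold (in DESeq2) and 8 turned.

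With 1 library left out, the striatum list ranged from -0.37 to 0.89, the mitochondrial list from -0.0723 to 0.40, Adora2a from -0.0781 to 2.41, mt-Atp8 from -0.0658 to 0.54 and mt-Nd5 from -0.0495 to 0.49. Without BBP libraries 1 and 2 the medians turned for the mitochondrial (-0.13), unfolded protein (-0.0677), myelin (-0.11), striatum (-0.35) and isocortex (-0.13) lists, and the values turned for mt-Atp8 (-0.0908), mt-Nd5 (-0.13), Ighm (-0.26), Adora2a (-0.46) and Tbr1 (-0.11), from fewer libraries. The distance difference of 0.2 was -0.000211 with 1 minus the Spearman correlation and ranged from -4.04 to 6.67 with 1 library left out.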

Other observations

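All tests in this part were chosen only after the result was seen, except the test of transcript length in BBP library 2, which was set before its value was seen but after the lists called under the length correction were known. Which brain region each library holds besides hippocampus is open for BBP library 1. Its striatum list median was 1.60 relative to the corn oil mean, where the highest corn oil library had 0.363, and 19 of 21 striatum markers and 16 of 25 isocortex markers were highest in this library, against 22.1% of all genes tested. Of 43 markers of dentate, CA1, CA2 and CA3 neurons, 33 were lowest in it, against 20.2% of all genes. Tissue from neighbouring striatum and neocortex in this library is a candidate explanation, although 14 of the 21 striatum markers and 21 of the 25 isocortex markers had a mean of at least 1 FPKM in corn oil hippocampus, and 4 of each belong to another list as well. An effect of BBP shared by the treated animals is argued against for the striatum list by the other BBP libraries, of which the higher stood at -0.101.

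In BBP library 2, the 121 ribosomal and respiratory chain genes had a median deviation of -0.42 (95% interval -0.54 to -0.37). The intervals in this paragraph are over the genes of this 1 library and hold no spread between libraries. They treat genes as independent and are too narrow, since the estimated correlation between genes was 0.505 for the ribosomal list and 0.674 for the oxidative phosphorylation list. Other protein-coding genes of similar annotated transcript length and level had -0.0929 (95% interval -0.13 to -0.06), with a median length of 1633 against 1231 bases. Genes matched on length alone, with a median length of 1273 bases, had -0.12 (95% interval -0.16 to -0.09). Across genes, deviation and transcript length had a Spearman correlation of 0.0776 in this library. Each length is that of the longest annotated transcript, which need not be the one expressed. Neither match can therefore decide on transcript length bias in this library. The share of counts outside mitochondrial genes and their nuclear copies fell by 0.0758 on the log2 scale, against a median of -0.51 (95% interval -0.63 to -0.46) for both lists without TMM factors, which argues against mitochondrial reads taking up counts as the whole cause. An effect of BBP shared by the treated animals stays open, since 2 of the 3 BBP libraries lay below the lowest corn oil library for the ribosomal list. For BBP library 3, at -0.17 against -0.09 in the matched genes and with a correlation of 0.205 between deviation and length across genes, length bias stays open too.

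Ttr and the other 22 choroid plexus markers had a Spearman correlation of 0.6 over the 6 libraries (exact permutation p = 0.242) and a Pearson correlation of 0.909 (exact permutation p = 0.0347), which was -0.589 without corn oil libraries 2 and 3. Choroid plexus tissue carried into the dissected hippocampus in varying amounts could account for the lower Ttr in BBP, but the relation rests on those libraries, and the gap between corn oil library 1 and the BBP libraries is left open. A change of Ttr alone is argued against for corn oil library 3, where 16 of the 22 other markers were highest (3.67 by chance). Of the 23 markers, 8 had a mean of at least 1 FPKM in corn oil and 3 belong to another list. An effect of BBP on choroid plexus was not told apart from this by any test here.

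With 3 libraries against 3 there are 10 splits, and the share of splits with a result as large can never be under 0.1. The counts of splits as large given here include the real split. The real split gave 0 genes past the threshold in edgeR (685 at an unadjusted p under 0.05, 0 in limma, 4 in DESeq2), and the highest other split gave 2. Under the looser description it gave 146 genes and the highest other 302, with 7 splits as large. It gave 18 lists and the highest other 18, with 2 splits as large. For GO terms it gave 68 and the highest other 27 (1 split as large), for KEGG 10 and 12 (2 splits), and for Reactome 137 and 106 (1 split).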
